A study of Homo sapiens with 12 samples.

How the data were processed

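Mono Mac 6 cells were differentiated with TGF-β1 and calcitriol, with or without LPS, and ChIP-seq was done with an antibody against 5-lipoxygenase in 3 samples per condition, with 3 input samples per condition, per the labels. The submitters' processing notes name Bowtie2, MACS2 and the build GRCh38 (hg38), with no versions. Whether duplicates were removed, and which control MACS2 used, is not given in the sources used here. The deposited values are 2 lists of MACS2 summits, 1 per condition, each giving a position of 1 bp, a peak name and the −log10 of the q-value that the authors' caller gave the peak. The unit was read from the file layout and from the lowest values, which lie just above the −log10 of 0.05. The labels tie each list to all 3 antibody samples of its condition, whereas the peak names carry the stem of a single replicate, numbered 1 in the LPS list and 2 in the unstimulated list. It is therefore not known whether the replicates were pooled or the lists came from different ones. Each condition was therefore treated as 1 sample, with no test between conditions and no replicate error. Peak borders, heights and fold enrichments, signal tracks, read totals and the input libraries were not used here. The depth of each library is thus unknown and was not held equal between the lists.

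Samples were grouped by the labels into 4 groups of 3. The protocol and the series design give 2 h of LPS and the sample characteristics 6 h, and neither could be preferred. Groups, tests, gene lists and alternatives were fixed before the data were examined, with the exceptions given below. The annotation used was a RefSeq gene table of GRCh38.p14 with 59675 genes with coordinates on chromosomes 1 to 22, X and Y, holding gene starts and ends without strand, exons or untranslated regions. All 396 symbols of the 12 gene lists matched, and the lists were tested over 19970 protein-coding genes. The non-coding members MALAT1 and NEAT1 were left out of that test. They had 6 LPS summits each, and 1 and 3 unstimulated summits.

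The absence of peak borders, strand and genome sequence changed the plan as follows. Peaks overlapping by at least 1 bp were replaced by summits within 500 bp. A summit within 1 kb of a transcription start was replaced by 1 within 1 kb of either end of a gene. The flank upstream of a gene was replaced by 5 kb on each side. Exons, introns and untranslated regions were not told apart. Base composition, motifs, repeats and placements matched on base composition were not analysed. Assembly gaps were approximated by leaving out 29 stretches of more than 2 Mb without an annotated gene (206 Mb in all), which left 2881 Mb for random placement.

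Sharing between lists and the share of summits at gene boundaries were set beside 1000 random placements of each summit on its own chromosome, or 200 for subsets, classes of genes and alternatives. Displaced positions were drawn 100 or 200 times, and gaps between neighbouring summits came from 100 placements. Wilson 95% intervals were computed for shares. For each gene list, members with a summit were counted and compared with 10000 random lists of protein-coding genes matched in 20 bins of gene length. Two-sided permutation p-values, from random reassignment of genes to lists within length bins, were adjusted by the Benjamini-Hochberg method over the 12 lists of a condition, and for the split over the lists with a summit at the setting (11 at equal list length, 9 at gene boundaries and 12 otherwise), and 0.0002 is the smallest unadjusted p that 10000 lists can give. Genes are not independent replicates, and neighbouring genes can share a summit, as IL23A with STAT2 and LTB4R with LTB4R2, so these p-values describe the lists and not the spread between cultures. The split into LPS-only and unstimulated-only members compared list members that had a summit with other genes that had one, in 5 bins of gene length. Summits less than 10 kb apart were stitched into regions. Most regions with many summits are not reported here. Chromosomes were compared per protein-coding gene and per Mb of placeable sequence. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

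The gene list test was tested on simulated data. With uniformly placed summits, as many as in the LPS list and in the unstimulated list, 1.0% and 2.0% of 200 lists of 40 genes drawn at random from the 19970 genes passed an unadjusted permutation p of 0.05, with 1000 random lists each. When 30% of the members without a summit were given one, 92.5% and 99.5% passed. The boundary share of uniformly placed summits was 0.957 and 0.950 of the random median. Unlike the real data, the simulated summits were not clustered and the simulated lists were random draws of genes. These rates therefore show that the test runs as intended and do not measure false calls in the real lists.

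Genes were named by a rule set before the data were examined. It took ALOX5, the genes nearest to the 8 strongest summits of the LPS list, the unstimulated list and the shared summits, up to 4 members per gene list and condition with the strongest boundary summit (planned as promoter peak), and the 5 strongest boundary summits of the LPS-only and unstimulated-only sets. Other genes and regions are named with the statement that they were chosen after their values were seen. Alternatives tried were stricter thresholds, other distances for sharing and boundaries, protein-coding genes alone, other flanks, the strongest 50% of each list and merged summits. Added after the data were seen were a distance of 200 bp, the LPS list held to the length of the unstimulated list, displacement of summits by 10 to 100 kb, omission of chromosome 13, random lists matched also on the number of genes within 250 kb, stitching of summits, the genes with a divergent transcript and the split into LPS-only and unstimulated-only members.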

Results

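Chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against 5-lipoxygenase was carried out in Mono Mac 6 cells, a human monocytic leukaemia cell line. 5-Lipoxygenase, the product of ALOX5, starts the synthesis of leukotrienes from arachidonic acid. The cells had been differentiated for 72 h with 1 ng/mL TGF-β1 and 50 nM calcitriol, the active form of vitamin D. Part of the cultures also received lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor signalling, at 1 µg/mL. The labels give the LPS exposure as 2 h in the protocol and as 6 h in the sample characteristics. The 12 samples formed 4 groups of 3, namely antibody and input samples with and without LPS. The values came from 1 list of peak summits per condition, each treated as 1 sample, and the peak names of the lists carry different replicate numbers. The numbers of reads behind the lists are unknown. No p-value between conditions was therefore possible, and no spread between replicates could be given. Intervals are Wilson 95% intervals and cover counting error only, and neighbouring summits are not independent. The −log10 q of a summit is the authors' own value and was used to rank summits within a list, so a gap between the lists in this value is not a measure of change.

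The first question was where the antibody enriched chromatin in either state. In the LPS list the strongest summits lay beside SLC16A3, a lactate transporter gene, and CCDC57, both on chromosome 17 (positions 82217328 and 82213101 of GRCh38, −log10 q of 61.5 and 50.9). The NF-kB subunit gene RELB on chromosome 19 (45001663, 199 bp inside the gene, 43.3), the myosin gene MYO1G on chromosome 7 (44979715, 47.8) and PAN3 on chromosome 13 (28138936, 43.0) were also among the 8 strongest. The others were positions nearest to NXT1 on chromosome 20 (23335035, 48.4), THBS2 on chromosome 6 (169214360, 44.5) and TPRG1 on chromosome 3 (188948344, 43.1). The TPRG1 summit lay 48.9 kb from that gene and 705 bp from a boundary of the antisense transcript TPRG1-AS1. Without LPS the strongest summits lay in the cytoskeletal actin gene ACTB on chromosome 7 (5530379, 41.4), in NARF on chromosome 17 (82458317, 41.1) and at MIR142HG, the host transcript of the haematopoietic microRNA miR-142, on chromosome 17 (58332019, 39.9, with TSPOAP1 the nearest protein-coding gene). PAN3 (28138932, 38.2), RAB37 on chromosome 17 (74690077, 37.6), MS4A6A on chromosome 11 (60186116, 36.8), SPI1 on chromosome 11 (47358948, 36.6) and RASA3 on chromosome 13 (114067105, 35.9) completed its 8 strongest. Of these 16 summits, all but those near MS4A6A, SPI1, RAB37, RASA3 and THBS2 lay within 1 kb of the start or end of an annotated gene.

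ALOX5 itself carried summits in both lists. The gene spans positions 45374216 to 45446117 of chromosome 10, and 5 LPS and 4 unstimulated summits fell within it. A summit lay 330 bp inside the first annotated base in the LPS list (45374546, −log10 q of 7.38) and 318 bp inside it in the unstimulated list (45374534, 9.41), 12 bp apart. The strongest LPS summit at the gene lay 5.85 kb inside (45380066, 10.6) and had an unstimulated counterpart 1 bp away (6.85). The strongest unstimulated summit lay 45.7 kb inside the gene (45419889, 10.4), where the LPS list held no summit within 38.2 kb (38214 bp).

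**Figure D1:**
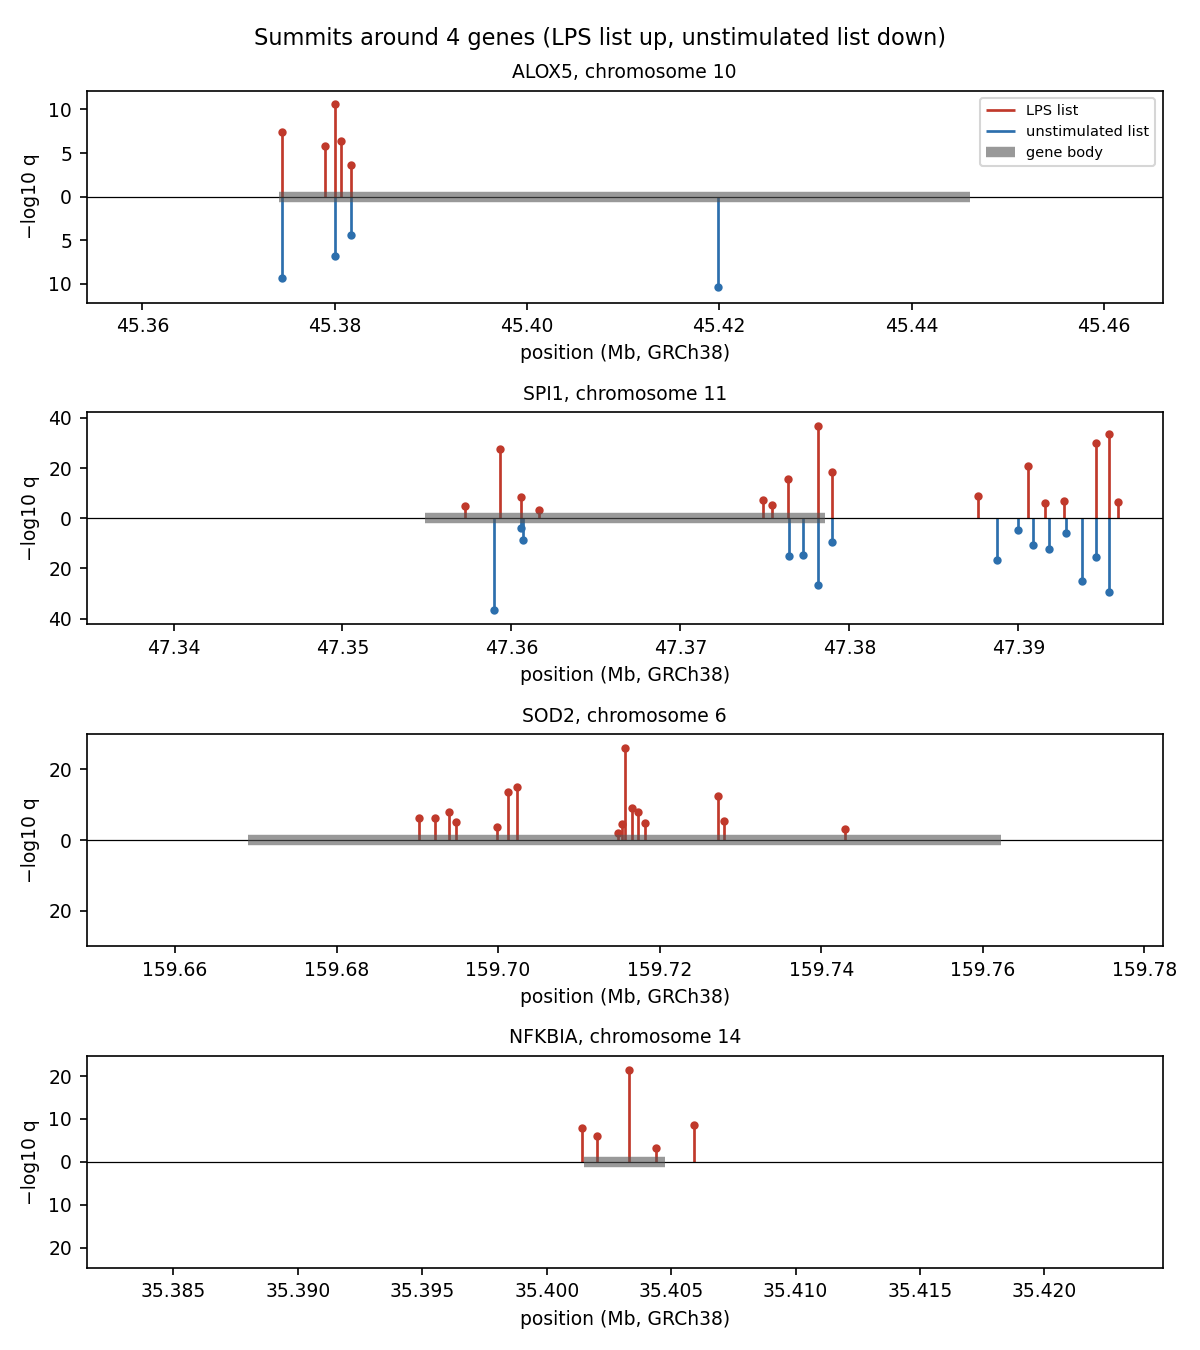
Summits within 20 kb of ALOX5, SPI1, SOD2 and NFKBIA, with position on GRCh38 in Mb on the horizontal axis and the authors' −log10 q of each summit on the vertical axis, LPS list upwards and unstimulated list downwards, and the gene body as a grey bar. ALOX5 and SPI1 carried summits in both lists, whereas SOD2 with 16 summits and NFKBIA with 5 carried them in the LPS list alone.

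The number of summits was 10318 with LPS and 4544 without, a ratio of 2.27. The median −log10 q was 5.36 in the LPS list and 6.31 in the unstimulated list. Summits were clustered in both. Of the gaps between neighbouring summits, 41.9% were shorter than 10 kb in the LPS list, against 3.84 to 4.80% in 100 random placements on the same chromosomes, and 38.2% in the unstimulated list, against 1.59 to 2.61%. The region with the most LPS summits ran over FLT3, a receptor tyrosine kinase gene, and PAN3 on chromosome 13 (28068518 to 28187856), with 38 LPS and 8 unstimulated summits. A region reaching into SRGN, which encodes the granule proteoglycan serglycin, on chromosome 10 (69045146 to 69101517) held 33 and 17. These regions were singled out after their counts were seen. At a q of 1e-05 or lower the ratio of the lists was 1.87.

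The second comparison asked which sites were common to both states. Summits at NARF, PAN3, RASA3, RAB11B, VAV1, CTSZ, and those nearest to DNAH17 and SLC39A13, were the 8 strongest that lay within 500 bp of a summit of the other list, ranked by the lower of their values. VAV1, a guanine nucleotide exchange factor of blood cells, had its shared summit on chromosome 19 (6773112, −log10 q of 34.1 with LPS and 29.96 without). The summits of RAB11B, a small GTPase gene, on chromosome 19 (8390545, 42.7 and 32.7) and CTSZ, a lysosomal protease gene, on chromosome 20 (59007593, 31.0 and 29.8) lay beside gene boundaries. The DNAH17 summit on chromosome 17 (78591469, 29.9 and 32.9) lay 14.1 kb from that gene, and the SLC39A13 summit on chromosome 11 (47395359, 33.8 and 29.3) lay 11.9 kb from its gene in the antisense transcript SLC39A13-AS1. Those of NARF (position 82458318, 41.5 and 41.1), PAN3 (43.0 and 38.2) and RASA3 (114067104, 34.8 and 35.9) lay 1 to 4 bp apart between the lists.

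Of the 4544 unstimulated summits, 2592 (57.0%, 55.6 to 58.5) had an LPS summit within 500 bp, against a median of 0.418% and a highest value of 0.792% in 1000 random placements. Of the 10318 LPS summits, 2623 (25.4%, 24.6 to 26.3) had an unstimulated summit within 500 bp. The share rose with strength. It was 75% in the strongest 25% of the unstimulated list and 45.1% in the weakest 25%, and 46.3% and 13.6% in the LPS list. When the LPS list was held to its 4544 strongest summits, 38.8% of unstimulated summits were shared.

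Summits found in 1 list alone included strong ones at gene boundaries. The 5 strongest of the LPS list lay at UST, a uronyl sulfotransferase gene, on chromosome 6 (149032414, −log10 q of 41.8, at a boundary of the antisense transcript UST-AS2), at HIVEP2 on chromosome 6 (142945932, 31.8), at ZSCAN16-AS1 on chromosome 6 (28137214, 30.3), at PRMT2 on chromosome 21 (46635852, 26.3) and at EMP3 on chromosome 19 (48325817, 23.7). In the unstimulated list they lay at DAZAP2 on chromosome 12 (51239015, 31.1), MYO1G on chromosome 7 (44978746, 22.5), RGS19 on chromosome 20 (64077591, 19.8, at a boundary of the microRNA gene MIR6813), CORO1A on chromosome 16 (30183821, 19.6) and THBS2-AS1 on chromosome 6 (169213547, 18.8). The unstimulated summits at MYO1G, RGS19 and THBS2-AS1 had LPS summits 558, 716 and 813 bp away, so those sites differed by the distance rule and not by the absence of a summit nearby.

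The third comparison set the summits against gene annotation. Within 1 kb of a gene start or end lay 2317 of the LPS summits (22.5%, 21.7 to 23.3) and 1094 of the unstimulated summits (24.1%, 22.9 to 25.3). Random placements gave medians of 7.14% and 7.28%, so gene boundaries held 3.14 and 3.31 times as many summits as placed at random. With each summit displaced by 10 to 100 kb instead, which keeps its neighbourhood, the ratios were 2.29 and 2.37. For boundaries of protein-coding genes alone they were 5.47 and 5.72 over random placement. A further 42.9% of LPS and 40.1% of unstimulated summits lay elsewhere within protein-coding genes, 8.78% and 9.86% within other genes, and 25.8% and 26.0% between genes. Shared summits lay at gene boundaries more often (26.9%, 25.3 to 28.6) than LPS-only summits (20.9%, 20.04 to 21.9) or unstimulated-only summits (20.4%, 18.7 to 22.3). Of 19970 protein-coding genes, 1611 had an LPS summit at a boundary (8.07%, 4.91 times the random median) and 796 an unstimulated one (3.99%, 5.27 times). Boundaries of long non-coding RNA genes carried 2.46 and 2.80 times the random number, those of microRNA genes 4.13 and 5.00 times, and those of pseudogenes fewer than at random, 0.694 and 0.619 times.

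Strand was not in the annotation used, so a transcription start could be told from a gene's far end only where a divergent transcript named after the gene marks it. There were 542 such genes of at least 6 kb. In the LPS list, 54 of them (9.96%, 7.72 to 12.8) had a summit within 1 kb of the end beside the divergent transcript and 3 (0.554%, 0.188 to 1.61) had one at the other end. In the unstimulated list the numbers were 29 (5.35%, 3.75 to 7.58) and 1 (0.185%, 0.0326 to 1.04). Within 500 bp the shares beside the divergent transcript were 6.27% and 3.14%, and with the strongest 50% of each list 6.27% and 3.51%. This comparison was added after the data were seen.

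**Figure D2:**
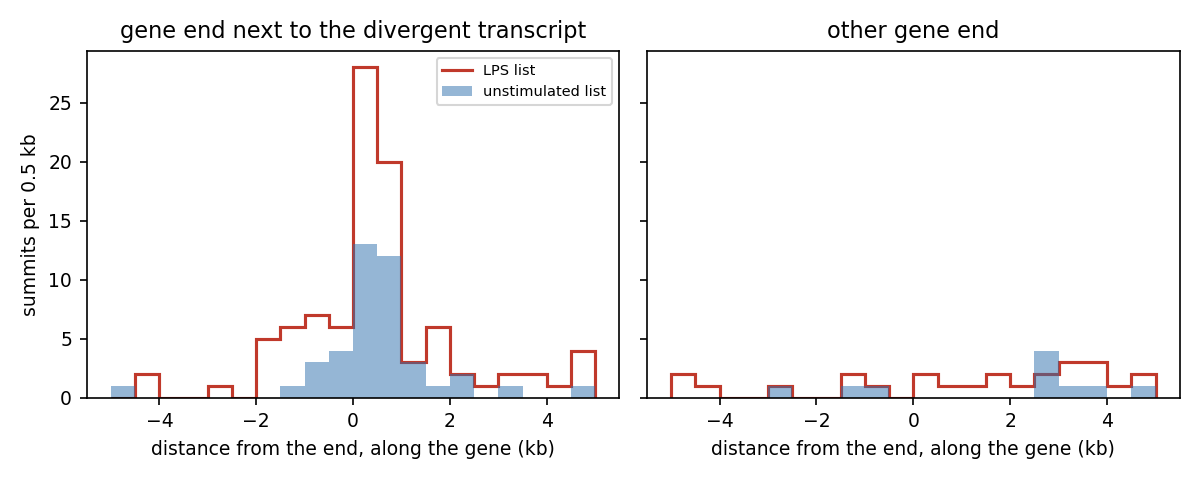
Summits per 0.5 kb (vertical axis) by distance in kb along the gene (horizontal axis, with positive values inside the gene beside the divergent transcript) around that end and around the other end of 542 genes, LPS list as a red line and unstimulated list as filled blue. The LPS list held 28 and 20 summits and the unstimulated list 13 and 12 in the first and second bins inside the end beside the divergent transcript.

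The fourth comparison asked which groups of genes carried summits in the gene body or within 5 kb of it, against random protein-coding gene lists of the same size and gene lengths. In the LPS and NF-kB response list, 43 of 58 members carried an LPS summit, where random lists held a median of 9 (adjusted permutation p = 0.0005 from 10000 random lists, as for every p of this comparison). Its strongest boundary summits lay at RELB, at the cytokine subunit gene IL23A on chromosome 12 (56339164, −log10 q of 22.2), at the AP-1 gene JUNB on chromosome 19 (12793082, 18.7) and at the NF-kB inhibitor gene NFKBIE on chromosome 6 (44264714, 13.6). Without LPS, 15 of the 58 members carried a summit (random median 5, adjusted permutation p = 0.0006). The strongest of these at boundaries lay at ZFP36, which encodes an mRNA-destabilising protein, on chromosome 19 (39410042, 13.5), at RELB (45001641, 11.99), at the Toll-like receptor gene TLR2 on chromosome 4 (153684506, 7.89) and at JUNB (12790743, 7.35).

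Members of this list with many LPS summits and no unstimulated summit, singled out after their values were seen, were SOD2, the mitochondrial superoxide dismutase gene, on chromosome 6 (159669069 to 159762281, 16 summits), TNIP1 on chromosome 5 (151029943 to 151087685, 13) and TNFAIP3 on chromosome 6 (137866349 to 137883312, 9), which both encode restraints of NF-kB signalling, NFKB1 on chromosome 4 (102501359 to 102617302, 7), the NF-kB inhibitor gene NFKBIA on chromosome 14 (35401513 to 35404749, 5) and the adhesion molecule gene ICAM1 on chromosome 19 (10271120 to 10286615, 5). Of others chosen in the same way, TNF (2 summits), CXCL8 (3) and CCL3 (3) had LPS summits alone, IL1B had 3 with LPS and 1 without, and IL6, IL10, IL12B, CCL5 and PTGS2 had none in either list. The strongest summits counted for TNF (31581257) and CXCL8 (73735818) lay outside the gene, in the flank of 5 kb. Neither gene had a boundary summit, whereas CCL3 had one (36088702, −log10 q of 6.81). Of the 44 members with a summit in either list, 29 had LPS summits alone, 14 had both and 1, FOSL1, named after its values were seen, had unstimulated summits alone. Genes with a summit drawn at random gave a median of 23 with LPS summits alone, and the difference missed the threshold (adjusted permutation p = 0.183). With the LPS list held to 4544 summits, 22 of 37 members had LPS summits alone against a random median of 12 (adjusted permutation p = 0.0176), and 1 had unstimulated summits alone against a median of 11 (adjusted permutation p = 0.0044). Counting gene boundaries or 20 kb on each side, the LPS-only share missed the threshold again (adjusted permutation p = 0.524 and 0.897). With 20 kb on each side the housekeeping list had fewer LPS-only members than random genes with a summit (10%, adjusted permutation p = 0.0072), which missed the threshold with 5 kb (21.1%, adjusted permutation p = 0.183). This split was added after the data were seen.

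**Figure D3:**
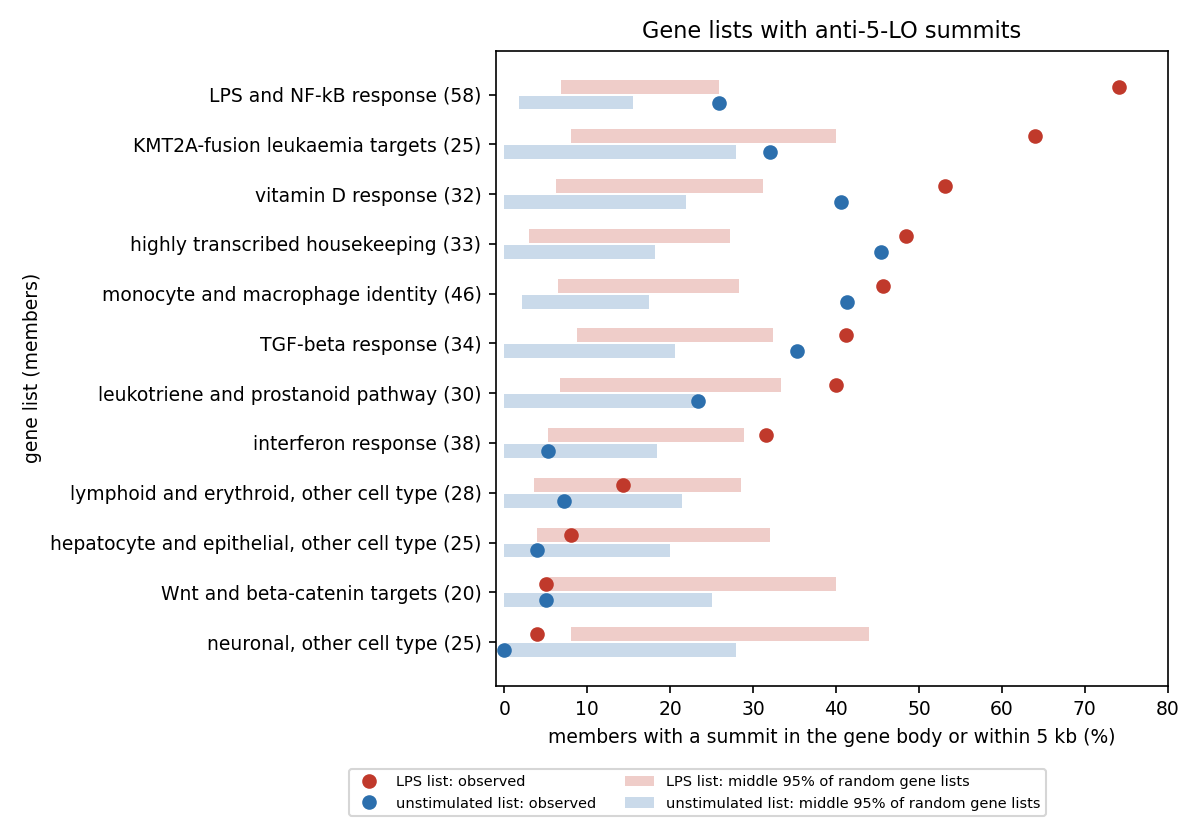
Share of each gene list's members with a summit in the gene body or within 5 kb (horizontal axis, percent) for the 12 gene lists (vertical axis, members in parentheses), points for the observed share and bars for the middle 95% of 10000 random lists, LPS list in red and unstimulated list in blue. The LPS and NF-kB response list stood at 74.1% with LPS and 25.9% without, and the housekeeping list at 48.5% and 45.5%.

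The lists tied to the differentiation of these cells carried summits in both states. In the vitamin D response list, 17 of 32 members had an LPS summit (adjusted permutation p = 0.0005) and 13 an unstimulated one (adjusted permutation p = 0.0006). Named boundary summits lay at the phosphatase gene DUSP10 on chromosome 1 (221742616, −log10 q of 16.7), NINJ1 on chromosome 9 (93134011, 15.3), THEMIS2 on chromosome 1 (27886211, 14.5) and CD93 on chromosome 20 (23086203, 12.5) with LPS. Without LPS they lay at SEMA6B on chromosome 19 (4542521, 12.3), THEMIS2 (27886225, 11.8), the antimicrobial peptide gene CAMP on chromosome 3 (48223838, 11.4) and CD14, the LPS co-receptor gene, on chromosome 5 (140630816, 7.76). NINJ1, CD93 and SEMA6B also had boundary summits in the other list, and DUSP10 and CAMP had summits there more than 1 kb from their boundaries. The LPS summit of CAMP (48222371, 14.97) lay only just beyond 1 kb from an end of the gene (48223495). CD14 had 2 unstimulated summits and no LPS summit. In the TGF-beta response list, 14 of 34 members had an LPS summit (adjusted permutation p = 0.0112) and 12 an unstimulated one (adjusted permutation p = 0.0014). KLF10 on chromosome 8 (102655081, 22.7 with LPS, and 102654997, 10.6 without), SKIL on chromosome 3 (170358069, 17.95, and 170358058, 23.7) and the ubiquitin ligase gene SMURF1 on chromosome 7 (99143792, 12.9, and 99143922, 8.02) had boundary summits in both lists, as did JUNB, which this list shares with the LPS and NF-kB response list.

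In the monocyte and macrophage identity list, 21 of 46 members had an LPS summit (adjusted permutation p = 0.0005) and 19 an unstimulated one (adjusted permutation p = 0.0006). SPI1, which encodes the myeloid transcription factor PU.1 (chromosome 11, 47354860 to 47378547), had 9 LPS and 7 unstimulated summits, with boundary summits 20 bp apart at 47378170 (36.7) and 47378150 (26.5). The azurocidin gene AZU1 on chromosome 19 had summits in both lists (828210, 18.3, and 828068, 27.4). CEBPD on chromosome 8 (47738757, 16.9) and S100A9 on chromosome 1 (153358569, 9.07) had LPS summits alone, and CEBPA (33299288, 9.66) and the neutrophil elastase gene ELANE (852814, 9.17), both on chromosome 19, had unstimulated summits alone. The leukotriene and prostanoid pathway list had 12 of 30 members with an LPS summit (adjusted permutation p = 0.0202) and 7 with an unstimulated one (adjusted permutation p = 0.0891). These counts include COTL1, with a summit in both lists, and DICER1, with an LPS summit alone, which are not themselves genes of this pathway. With boundary summits alone the LPS list stood at 2.5 times the random median and missed the threshold (adjusted permutation p = 0.326), and the unstimulated list stood at 5.0 times and passed it (adjusted permutation p = 0.0302). With 10 kb on each side the LPS call was lost at 1.71 times the random median against 2.0 times before (adjusted permutation p = 0.0561). With the strongest 50% of the unstimulated list a call was gained at 3.0 times against 2.33 times before (adjusted permutation p = 0.0312). ALOX5AP, whose product presents arachidonic acid to 5-lipoxygenase, on chromosome 13 (30713836, 17.9, and 30713826, 13.9) and the leukotriene C4 synthase gene LTC4S on chromosome 5 (179793461, 14.8, and 179793550, 14.2) had boundary summits in both lists. PTGES3 on chromosome 12 (56687879, 9.19) had an LPS summit alone, and the leukotriene B4 receptor gene LTB4R on chromosome 14 (24311683, 6.43) an unstimulated summit alone. That summit was also counted for LTB4R2. Both genes were thus among the 5 members with an unstimulated boundary summit through 1 summit, which weakens the call at boundaries.

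In the interferon response list, 12 of 38 members had an LPS summit (adjusted permutation p = 0.0304) and 2 an unstimulated one (adjusted permutation p = 0.749). GBP5 on chromosome 1 had both (89273855, 30.8, and 89273651, 6.31), whereas the antiviral genes MX1 (41420832, 10.5) and MX2 (41362990, 6.25) on chromosome 21 and IRF9 on chromosome 14 (24161441, 9.70) had LPS summits alone. Of 12 members with a summit in either list, 10 had LPS summits alone, against a random median of 6 (adjusted permutation p = 0.183). At equal list length it was 4 of 6 against 2 (adjusted permutation p = 0.4455), so this split missed the threshold in both settings. The LPS call was lost with 10 kb on each side (adjusted permutation p = 0.0629), with the strongest 50% of the list (0.0891) and at equal list length (0.336), with 1.86, 2.0 and 2.0 times the random median against 2.0 times before. Among targets of KMT2A fusions, an oncogenic lesion of monocytic leukaemias, 16 of 25 members had an LPS summit (adjusted permutation p = 0.0005) and 8 an unstimulated one (adjusted permutation p = 0.0408). FLT3 on chromosome 13 (28100091, 12.9), ZEB2 on chromosome 2 (144519731, 7.54) and CDK6 on chromosome 7 (92604534, 3.39) had LPS boundary summits, and ZEB2 (144519723, 8.94), MYB on chromosome 6 (135181570, 4.75) and JMJD1C on chromosome 10 (63522058, 3.68) unstimulated ones. Counting boundary summits alone ended both calls of this list (1.5 and 3.0 times the random median, adjusted permutation p = 0.679 and 0.195, against 2.67 times in both before). The unstimulated call was also lost with 10 kb on each side and without chromosome 13 (2.67 and 2.33 times, adjusted permutation p = 0.054 and 0.07).

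The list of highly transcribed housekeeping genes had 16 of 33 members with an LPS summit (adjusted permutation p = 0.0005) and 15 with an unstimulated one (adjusted permutation p = 0.0006). TUBA1B on chromosome 12 (49131155, 21.6, and 49131162, 35.5) and ACTB (5530364, 18.2, and 5530379, 41.4) had boundary summits in both lists. FTL on chromosome 19 (48964622, 19.4) and ACTG1 on chromosome 17 (81513388, 11.0) were among the strongest with LPS, and PKM on chromosome 15 (72231012, 14.4) and EEF1A1 on chromosome 6 (73520692, 12.6) without. FTL, ACTG1, PKM and EEF1A1 also had boundary summits in the other list. Of its members, 14 had no summit in either list, among them all 7 ribosomal protein genes (RPL3, RPL4, RPL13A, RPLP0, RPS3, RPS6 and RPS18), EEF2, NPM1 and NCL, named after their values were seen. No list of another cell type lay above random lists. The neuronal list had 1 of 25 members with an LPS summit, below the random median of 6 (adjusted permutation p = 0.0219), and 0 with an unstimulated one (adjusted permutation p = 0.0942). Its LPS call was lost with boundary summits alone, with the strongest 50% of the list and at equal list length (adjusted permutation p = 0.387, 0.0564 and 0.0816). In each of these settings the ratio to the random median was 0.0, against 0.167 before. The hepatocyte and epithelial list had 2 and 1 of 25 (adjusted permutation p = 0.38 and 0.749), and the lymphoid and erythroid list 4 and 2 of 28 (adjusted permutation p = 1.0 in both), with NKG7 (51372493, 20.02, and 51372505, 10.9) and KLF1 (12884389, 10.4, and 12884190, 7.39), both on chromosome 19, named by the rule. The Wnt and beta-catenin target list had 1 of 20 in either state (adjusted permutation p = 0.108 and 0.749). In all, 8 of the 12 lists lay above random lists with LPS and 6 without. The random lists were matched on expression in no setting, and the housekeeping list itself stood at 4.0 and 7.5 times the random median. Whether the other calls go beyond the activity of these genes in the cells was therefore not tested. Lists also share members, such as CD14, CEBPB and ITGAM in the vitamin D response and the monocyte and macrophage identity lists.

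The last comparison concerned the spread of summits over chromosomes. Chromosome 13 carried 515 LPS and 193 unstimulated summits, which is 1.52 and 0.571 per protein-coding gene, or 2.95 and 2.51 times the genome's value. Chromosome 21 followed with 1.72 and 2.08 times. The lowest ratios were on chromosomes X (0.233 and 0.264), 22 (0.425 and 0.331) and 16 (0.415 and 0.489). Per Mb, chromosome 13 held 1.48 (1.36 to 1.61) and 1.26 (1.09 to 1.44) times the genome's value. Chromosomes 19 (2.99 and 3.12), 17 (2.06 and 2.56), 20 (1.61 and 1.93) and 21 (1.48 and 1.79) lay above it in both lists and chromosome 1 (1.41) without LPS, so chromosome 13 stood highest per gene and not per Mb. Of its protein-coding genes, 25.1% had an LPS summit and 13.9% an unstimulated one in the gene or within 5 kb, against 19.3% and 10.1% of all.

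**Figure D4:**
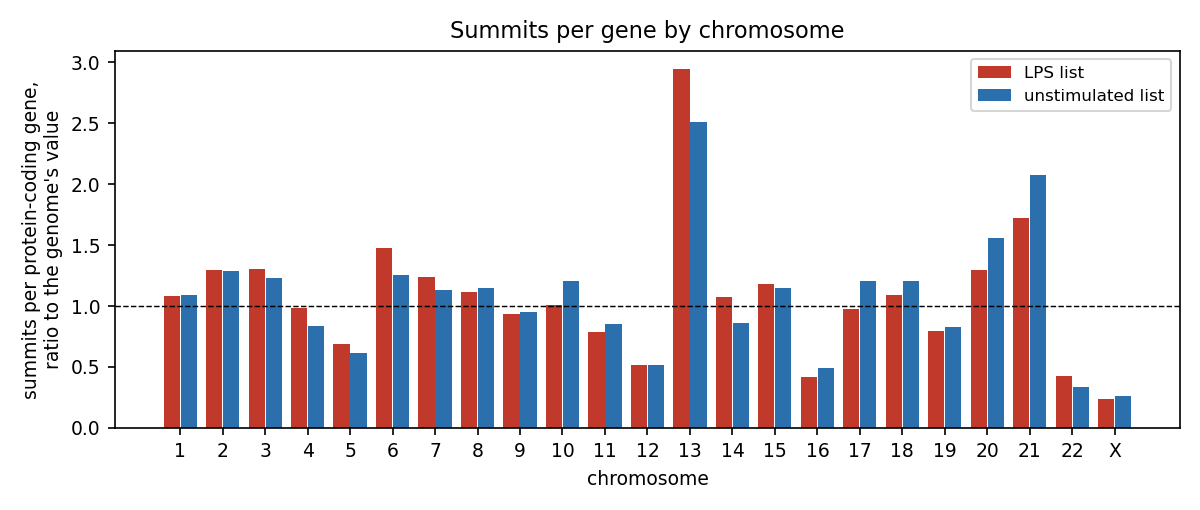
Summits per protein-coding gene as a ratio to the genome's value (vertical axis) for chromosomes 1 to 22 and X (horizontal axis), LPS list in red and unstimulated list in blue, with the genome's value at the dashed line. Chromosome 13 stood highest at 2.95 and 2.51 and chromosome X lowest at 0.233 and 0.264.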

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

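The LPS-only split, the genes with a divergent transcript, equal list length, displacement, stitching, the 200 bp distance, gene density matching and omission of chromosome 13 were chosen after the data were seen. No paired analysis was possible because each condition had a single list with no values per replicate, and for the same reason no replicate was left out. Placements matched on base composition, omission of peaks rich in repeats, and the windows and backgrounds planned for motifs and base composition were not run. The depth behind the lists is unknown and limits every comparison of their lengths.

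The LPS list kept 5159 summits at or above its own median value and 5575 at a q of 1e-05 or lower, and the unstimulated list 2813 and 2986, by construction of the stricter thresholds. The ratio of the lists stayed above 1.5 throughout, between 1.83 and 2.27. The share of unstimulated and of LPS summits that were shared was 51.0% and 22.5% at 50% reciprocal overlap of 500 bp windows, 48.8% and 21.5% within 200 bp, 70.8% and 37.2% with summits extended by 1 kb on each side, 53.2% and 23.5% for the strongest 50% of each list, and 38.8% and 38.0% at equal list length. The ratio to random placement at gene boundaries, LPS list first, was 3.59 and 3.91 within 500 bp, 2.21 and 2.29 within 2500 bp, 5.47 and 5.72 for protein-coding genes alone, 3.58 and 3.87 for the strongest 50%, and 2.29 and 2.37 with displaced summits. The number of gene lists above random ranged from 6 to 8 with LPS and from 5 to 7 without. The share of LPS and NF-kB response members with LPS summits alone was 65.9% and missed the threshold (adjusted permutation p = 0.183). It was 59.5% and passed at equal list length (adjusted permutation p = 0.0176), and it was 66.7% at gene boundaries and 54.3% with 20 kb on each side, where it missed the threshold (adjusted permutation p = 0.524 and 0.897). On chromosome 13 the LPS ratio per gene was 3.34 after stitching. Except where a threshold removed summits, the cause was not tested. Apart from that list's split, 167 alternatives were run for single gene lists and gene sets. Of these, 148 stayed on the same side of the threshold or within the interval, 12 lost the call, 3 gained it and 4 moved a value beyond its interval, and no called list changed direction.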

Other observations

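The tests of the strongest 25% of unstimulated summits, of stitched regions on chromosome 13, of gene density and of the housekeeping list, the counts of genes with summits in 1 list alone, and the LPS-only split were chosen only after the result or a closely related value was seen. The value per Mb on chromosome 13, the need for repeat calls and the ribosomal protein genes were added to the tests of gene density, of a more sensitive call and of the housekeeping list after their first results were seen, and left open explanations that the first rules had excluded, or in the last case had favoured. Genes and counts named next were likewise chosen after their values were seen.

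Genes both within and outside the fixed lists carried many summits in 1 list and none in the other. There were 53 protein-coding genes with at least 5 LPS summits in the gene or within 5 kb and no unstimulated summit, and 1, the urea transporter gene SLC14A2 (8 summits), with the opposite. With the LPS list held to 4544 summits the numbers were 12 and 9. Beside SOD2, TNIP1 and TNFAIP3, the first group held IDO2, a tryptophan-catabolising enzyme gene (15 summits), UST (13), BMPER (13), the protein kinase C gene PRKCH (11), RASSF5 (9) and ADAM17, whose product releases TNF from the cell surface (7). PLA2G4A, which encodes the cytosolic phospholipase that frees arachidonic acid (chromosome 1, 186828949 to 186988981), had 10 LPS summits, and the thromboxane synthase gene TBXAS1 on chromosome 7 (139778242 to 140020293) had 6, neither with an unstimulated summit. Among members of the fixed lists, the unstimulated list held more summits at MPO (4 against 1) and the TGF-beta receptor gene TGFBR2 (7 against 1), and LYZ, PRTN3 and CYP24A1, the vitamin D catabolic enzyme gene, had summits there alone. LYZ and CYP24A1 had 1 each. The 2 counted for PRTN3 lay outside that gene within 5 kb and were also those counted for its neighbour ELANE. These counts carry no replicate error.

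The longer LPS list was the first pattern weighed. A more sensitive call of the same sites stays open. Of the 1136 strongest 25% of unstimulated summits, 953 had an LPS summit within 2 kb (83.9%, 81.6 to 85.9), below the 95% first set for this explanation, but the share that repeat calls of 1 condition would reach is unknown. Splitting of the same regions into more summits argues for a ratio near 1 after stitching, and the ratio of regions was 2.13 (6007 against 2816). Sequencing depth and pull-down efficiency, for which the lists hold no value, a difference between the replicates behind the lists and the LPS treatment itself stay open.

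The second pattern was the LPS and NF-kB response list. A longer LPS list alone would leave the LPS-only count of these genes within random lists at equal length. At equal length that count lay at the 99.955 percentile (adjusted permutation p = 0.0176). However, this setting kept the strongest LPS summits and the whole unstimulated list, so it changed summit strength together with length. The LPS-only share missed the threshold with the full lists, at gene boundaries and with 20 kb on each side (adjusted permutation p = 0.183, 0.524 and 0.897). Whether list length alone gives the pattern therefore cannot be decided. A gathering of summits at highly transcribed genes, whatever the antibody binds, stays open. The housekeeping list lay at the 100.0 percentile in both lists, but all 7 of its ribosomal protein genes had no summit, and the list does not bear on LPS-only summits. Input signal was not analysed here, so a biological explanation by 5-lipoxygenase recruitment remains an untested hypothesis.

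The third pattern was chromosome 13. Clusters with gaps under 10 kb would merge on stitching, but regions per gene stayed at 2.87 times the genome's value or more in both lists. Clusters spread over wider stretches would not merge, so a few broad regions stay open. In the LPS list the 5 Mb bin starting at 25 Mb held 128 of the chromosome's 515 summits. Low gene density stays open for at least part of the pattern, since the ratio fell from 2.95 and 2.51 per gene to 1.48 and 1.26 per Mb, although the highest ratio per gene was 1.2 on chromosomes 4, 5, 18 and X, of which 18 came nearest in density (3.62 against 3.50 genes per Mb). Extra copies of the chromosome in this cell line remain open too. Of 16 bins of 5 Mb, 10 (62.5%) lay above the genome's median bin in the LPS list and 11 (68.75%) in the unstimulated list. These shares lie between what many copies and a few regions would give. Bins with fewer than 5 protein-coding genes were left out, so summits in the most gene-poor stretches of the chromosome were not counted. The input samples, which bear on copy number, were not analysed here, and no biological explanation was tested.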
